A study of Mus musculus with 12 samples.

How the data were processed

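Gene expression was measured in total RNA from 4 groups of mouse cells, with 3 Illumina BeadChip arrays per group and 12 arrays in all. The groups were primary embryonic fibroblasts of strain FVB/N carrying neomycin resistance (MEF), sphere cells that the labels describe as converted from such fibroblasts at passage 5 and at passage 15, and J11 embryonic stem cells of another mouse strain (MES), which the study took as its reference. RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, and labelled as biotinylated cRNA, per the labels. The arrays came from 3 chips. All MES and passage 15 arrays were on chip 1, replicates 1 and 2 of the MEF and passage 5 groups were on chip 2, and replicate 3 of both was on chip 3.

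The deposited raw table holds, for each array, a bead-summary intensity per probe on a linear scale, not normalized between arrays and with background already subtracted, since every array reaches values below 0. Its companion columns hold, per the file headers, a detection p-value per probe, taken against negative control beads. A further table made by the authors holds log2 values that were quantile normalized over all 12 arrays, with array medians between 5.956 and 5.959. The tool, the offset and the background step behind that table are not given in the sources used here. The series matrix holds the same log2 values as that deposited table (largest difference 0).

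Raw intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, using an offset of 16 and negative controls inferred from the detection p-values. Of 46657 probes in the tables, 20 were left out because a spreadsheet had turned a value of passage 15 replicate 3 into a date, which left 46637. The platform annotation gave 1 gene symbol to 22380 probes, several symbols to 0 and no gene to 24277. All 22380 annotated probes matched a RefSeq gene by Entrez ID, and this changed 0 symbols. Probes were kept if the detection p was under 0.05 on all 3 arrays of at least 1 group. This kept 19444 probes, of which 12156 had a gene. Each gene was represented by its brightest kept probe, giving 9343 genes. Of the 24271 analysed probes without a gene, which were 52% of the probes, 7288 passed the same filter and are not analysed here. Nanog, a core pluripotency factor, had 0 probes in the annotation used.

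A linear model with 1 mean per group was fitted to all 12 arrays with limma (lmFit, contrasts.fit and eBayes without a trend, 8 residual and 4.98 prior degrees of freedom). It was used for 6 comparisons between pairs of groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison together with a change of at least 2-fold, which is 1 on the log2 scale. Errors given as SE come from this model and those given as SD are between the 3 arrays of a group. Where the probe used for a gene was above background on none or 1 of the 3 arrays in 1 of the groups compared, its change is given as at least a number of fold, computed against the background level of the arrays. Extending this to 1 of 3 arrays was chosen after the values were seen. Such a bound holds for the probe used, and another probe of the gene can show less change. List medians with bounds use bounds only for genes with every probe below background on all arrays of a group. The genes, filters, tests and alternatives were chosen before the data were examined, apart from those named below as chosen later.

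Genes are named by a rule with 3 parts. Named everywhere are 10 genes: Pou5f1, Nanog, Sox2, Klf4, Myc, Zfp42, Col1a1, Vim, Cd44 and Thy1. Named per comparison are the 6 genes with the largest rise and the 6 with the largest fall among called genes whose arrays did not overlap between the groups, leaving out clone, predicted and locus symbols. Named per gene list are up to 4 called members with the largest absolute change, or the 2 largest changes where no member was called. Not every gene that the rule allows is printed. A few genes outside the rule are named as such.

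The 30 gene lists, written from textbook knowledge, covered pluripotency, fibroblast matrix and surface, contractile and TGF-beta targets, mesenchymal transcription factors, epithelial junction and keratin, neural and neural crest, endoderm, mesoderm, adipocyte and lipid storage, bone and cartilage, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR targets, cell cycle, p53 targets and cell cycle arrest, interferon response and antigen presentation, chemokine and inflammation, glycolysis and hypoxia, ATF4 and unfolded protein response, NRF2 targets, Hox genes, imprinted genes, germline, macrophage and blood, endothelial, skeletal muscle, keratinocyte, immediate early and heat shock, housekeeping, and sex-linked genes. Of these, 26 were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 within each comparison. Housekeeping and sex-linked genes were set aside as controls. The macrophage and keratinocyte lists had fewer than 3 measured genes. Each camera test was also run with the correlation estimated per list. Calls within a list were counted with adjustment over all genes and adjusted over the list alone.

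For the genes called between MEF and MES, the position of each sphere array was the median over genes of its distance from the MEF mean divided by the distance between the MES and MEF means, so that 0 is the MEF level and 1 the MES level. Positions at the passages were compared by an exact two-sided permutation test, for which 0.1 is the smallest p that 3 against 3 arrays allow.

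Alternatives were the authors' normalized table, no background correction, median scaling of each array, no filter on dim probes, a stricter detection p of 0.01, the mean over the probes of a gene, a variance trend, no fold threshold, a fit to the 2 groups compared alone, chip as a random or fixed block, the replicate number as a block, and leaving out each array in turn. Leaving out both chip 3 arrays was added after those arrays were seen to stand apart. The series matrix was not run apart from the authors' table, since its values are equal. Replicate numbers follow the order of deposit and were not taken to pair samples: correlations between same-numbered arrays of different groups, after subtracting group means, ran from −0.0891 to 0.272. The model fit was tested on simulated values of 9343 genes, of which 100 were changed by 1.5 and 100 by 2.5 on the log2 scale. It recovered 90% to 97% of the changes of 1.5 and called between 0 and 3 unchanged genes per comparison. The simulation began from normalized gene values, so normalization, filtering and the choice of probe were not tested. For arrays, the number of replicates limits the precision. P-values measure only the spread between these arrays, since nothing in the labels says that replicates were separate cultures.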

Results

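Transcript levels were measured on 12 bead arrays, 3 for each of 4 groups of mouse cells: embryonic fibroblasts (MEF), sphere cells at passage 5, sphere cells at passage 15, and J11 embryonic stem cells (MES). The spheres had been converted from fibroblasts in a medium containing AlbuMAX I, a lipid-rich serum albumin. Each array detected between 15761 and 19060 probes, 33.8% to 40.9% of those analysed, with 15761 to 17234 on chip 1 and 17910 to 19060 on the other chips. Median raw intensity ran from 3.8 to 9.4. Arrays of the same group correlated at 0.976 to 0.996 across genes, which are not independent replicates. Passage 15 spheres were closest to MES (median r 0.959, range 0.946 to 0.974) and farthest from MEF (0.869, range 0.81 to 0.886). Passage 5 spheres lay at similar distances from MEF (0.923, range 0.882 to 0.965), passage 15 spheres (0.923, range 0.913 to 0.935) and MES (0.933, range 0.921 to 0.943). The first principal component held 60.9% of the variance and the next 18%.

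Transcripts of pluripotent cells were present in all 4 groups, including the arrays labelled MEF. Of 26 pluripotency genes on the array, 22 passed a detection p of 0.01 on all 3 arrays labelled MEF, 22 at passage 5, 23 at passage 15 and 22 in MES. Of 14 macrophage and blood genes, 1 did so in each group. Pou5f1, the transcription factor Oct4, had a mean log2 intensity of 11.55 ± 0.47 (SD, n = 3) in arrays labelled MEF, 11.41 ± 0.32 at passage 5, 12.61 ± 0.17 at passage 15 and 12.69 ± 0.08 in MES. Zfp42, a marker of the naive pluripotent state also known as Rex1, stood at 10.96 ± 0.44, 11.06 ± 0.11, 11.14 ± 0.18 and 10.32 ± 0.31 in the same order. Sox2 stood at 8.22 ± 0.42, 9.08 ± 0.09, 9.20 ± 0.06 and 8.44 ± 0.32. Because of these transcripts, whose origin was not settled, the group is called arrays labelled MEF, and its comparisons are not taken as a pure fibroblast baseline.

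Col1a1, the main chain of type I collagen, fell from 13.22 ± 0.57 (SD, n = 3) in arrays labelled MEF to 6.98 ± 1.09 at passage 5 and was not above background at passage 15 (4.80 ± 0.22), against 6.40 ± 0.25 in MES. Thy1, a fibroblast surface marker also found on mouse embryonic stem cells, stood at 11.7 ± 0.45, 8.12 ± 1.82, 5.42 ± 0.03 and 9.19 ± 0.22. The 3 arrays of passage 5 differed widely in both genes. Sox17, a transcription factor of endoderm, was above background at passage 5 alone (8.68 ± 0.32).

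**Figure D1:**
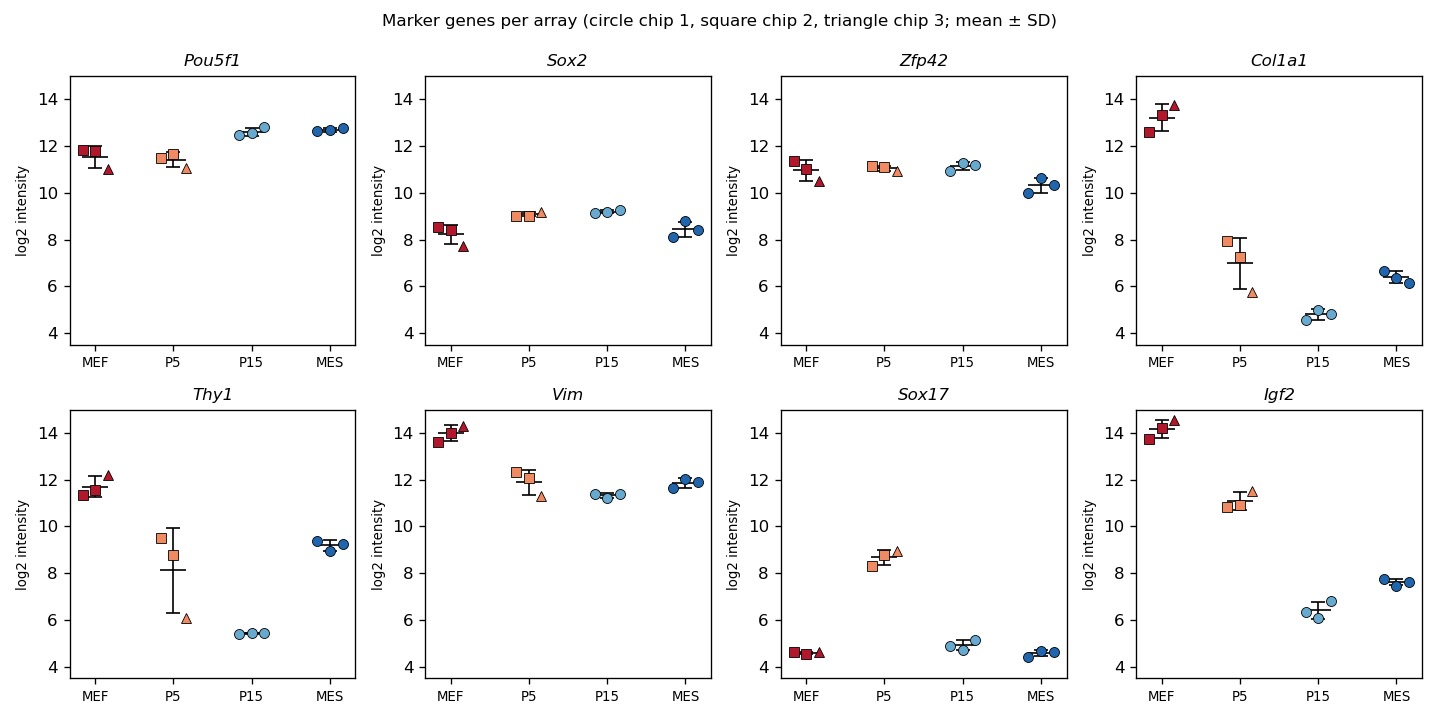
Log2 intensity of 8 genes on each of the 12 arrays, by group; circles are chip 1, squares chip 2 and triangles chip 3, and horizontal lines with bars give the mean and SD of 3 arrays. Col1a1 falls from 13.22 in arrays labelled MEF to 4.80 at passage 15, Sox17 peaks at passage 5 at 8.68, and Pou5f1 lies above 11 in every group mean.

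Arrays labelled MEF were first set against MES, the reference population of the study. The largest differences were of genes higher in the arrays labelled MEF: Col1a1 by 6.82 on the log2 scale (SE 0.42, n = 3 per group, adjusted p = 1.24e-07), Actg2, a smooth muscle actin, by at least 116-fold, the fetal growth factor Igf2 by 6.55 (SE 0.24), and Cav1, the coat protein of caveolae, by 6.27 (SE 0.46). Ccn4 was at least 70.9-fold higher and Cd44, the hyaluronan receptor, at least 15.4-fold higher, as neither was above background in MES by the probe used. Their other probes gave 0.76 for Ccn4 and 1.06 for Cd44 on the log2 scale. Pigt, an enzyme of GPI anchor assembly, was 66.2-fold higher by the probe used, while the lowest of its 2 probes gave 0.08 on the log2 scale. Vim, the intermediate filament of mesenchymal cells, was 4.37-fold higher and Thy1 5.72-fold higher (adjusted p = 0.00318).

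Genes higher in MES included Ucp1, by at least 6.44-fold, Igsf21 (log2 difference −2.88), the D-type cyclin Ccnd3 (−2.75), Prtg (−2.74), Tlx2 (−2.63) and the caudal homeobox gene Cdx1 (−2.61). The other probe of Ccnd3 gave −0.43 and that of Prtg −0.61. Pou5f1 was 2.21-fold lower in arrays labelled MEF (log2 difference −1.15, SE 0.21, adjusted p = 5.22e-04), but this fell short of 2-fold without MEF replicate 3 (−0.88) and with the mean over its probes (−0.57), as those probes differed in sign. Sox2 (−0.22, adjusted p = 0.352), Zfp42 (0.64), Klf4 (0.96) and Myc (−0.71) were not called. The other of the 2 Sox2 probes had the opposite sign (1.10). Klf4 passed 2-fold without MEF replicate 3 (1.14) or without MES replicate 2 (1.03).

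Of 24 measured fibroblast matrix and surface genes, 22 were called higher in arrays labelled MEF, the same number when adjusted over the list alone (median log2 difference 3.54, or 3.26 with genes below background at their bound, adjusted p = 4.50e-14, and adjusted p = 0.194 with an estimated correlation). All 12 contractile and TGF-beta targets were called higher, as were all 12 when adjusted over the list alone (median 3.83, or 3.66 with bounds, adjusted p = 9.29e-09, and adjusted p = 0.194 with an estimated correlation), among them Acta2 at 4.78 and Tagln at least 11.6-fold. By the lowest of its 3 probes Acta2 was at 0.86. All 13 chemokine and inflammation genes were called higher (13 adjusted over the list alone, median 3.56, or 3.08 with bounds, adjusted p = 1.71e-07, and adjusted p = 0.194 with an estimated correlation), led by the chemokine Cxcl12 at 4.78, or 0.64 by its other probe. Mesenchymal transcription factors followed with 5 of 6, both ways of adjusting (median 3.61, or 3.05 with bounds, adjusted p = 1.01e-04, and adjusted p = 0.194 with an estimated correlation), with Zeb2 at least 11.3-fold higher.

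Skeletal muscle genes were higher in 7 of 9 (median 2.67, or 2.04 with bounds, adjusted p = 2.27e-05, and adjusted p = 0.194 with an estimated correlation). Imprinted genes were higher in 7 of 12 with 1 lower (median 1.59, adjusted p = 8.48e-05, and adjusted p = 0.194 with an estimated correlation). Hox genes were higher in 7 of 14 (median 1.02, or 0.92 with bounds, adjusted p = 3.45e-04, and adjusted p = 0.194 with an estimated correlation), and ATF4 and unfolded protein response genes in 7 of 13 with 1 lower (median 1.29, or 1.07 with bounds, adjusted p = 7.47e-04, and adjusted p = 0.194 with an estimated correlation). Chac1, a glutathione-degrading enzyme induced by ATF4, was 4.59 higher. Interferon response genes were higher in 6 of 12 (median 1.00, or 0.58 with bounds, adjusted p = 0.00111, and adjusted p = 0.194 with an estimated correlation). The same held for p53 targets in 4 of 12 (median 0.57, adjusted p = 0.017, and adjusted p = 0.194 with an estimated correlation, a call lost with the mean over probes, where the median was 0.16) and immediate early genes in 4 of 8 (median 1.00, adjusted p = 0.0235, and adjusted p = 0.194 with an estimated correlation). Counts adjusted over the list alone were the same for these 7 lists.

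Lists lower in arrays labelled MEF were germline genes, with 5 of 6 called (median −1.48, adjusted p = 0.00405, and adjusted p = 0.267 with an estimated correlation), and cholesterol synthesis, with 5 of 16 called including Insig1 at −1.82 and Mvd at −1.55 (median −0.68, adjusted p = 0.00774, and adjusted p = 0.287 with an estimated correlation). The cell cycle list also passed downward (median −0.51, adjusted p = 0.0402, and adjusted p = 0.404 with an estimated correlation), but its 4 called genes split evenly, with Plk1 at 2.26 and Pcna, the replication clamp, at −1.56, and it failed without MES replicate 2 or MEF replicate 3 (medians −0.53 and −0.39) and with the mean over probes (−0.51). Pluripotency genes did not pass (24 measured, 5 higher and 5 lower, median 0.04, adjusted p = 0.688). Lefty1, an inhibitor of Nodal signalling, was 2.25 higher in arrays labelled MEF.

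limma called 1992 of 9343 genes (21.3%), 1219 higher and 773 lower in arrays labelled MEF, and without a fold threshold the split turned to 2427 higher and 3398 lower. All MES arrays were on chip 1 and all arrays labelled MEF on chips 2 and 3, so group and chip cannot be told apart here, and the strains differed too. Of 26 lists, 14 passed with the preset correlation and 0 in camera with an estimated correlation, where 5 had an unadjusted p under 0.05.

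Passage 5 spheres and arrays labelled MEF shared chips, and their comparison asks what differed between these groups. Rises and falls, here and below, are differences between groups, with arrays labelled MEF not taken as a pure fibroblast baseline. The largest rises at passage 5 were of Srgn, the proteoglycan serglycin, by 5.12 on the log2 scale (SE 0.14, n = 3 per group, adjusted p = 2.14e-10), Foxq1 by 4.73 (SE 0.16), the gastrokine Gkn1 by at least 25.5-fold, Nostrin by 4.13 (SE 0.20), Sox17 by at least 13-fold and Gkn2 by at least 12.4-fold. The largest falls were of Col1a1 by 75.6-fold (log2 change −6.24, SE 0.42, adjusted p = 3.66e-07), Actg2 (−5.84), Col3a1 (−5.13), the semaphorin receptor Nrp1 (−5.04), Ccn4 (−5.02) and Acta1, the skeletal muscle actin (−4.76). Thy1 fell by 3.58 (SE 0.61), Cd44 by 3.37 (SE 0.39) and Vim by 2.08 (SE 0.24). By their other probes Ccn4 was −0.74 and Cd44 −0.97. Without passage 5 replicate 3, Col1a1 was −5.64, Actg2 −5.02, Ccn4 −4.10, Acta1 −4.08 and Thy1 −2.55. Without passage 5 replicate 1 Ccn4 was −5.66 and Thy1 −4.27.

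Of the pluripotency factors, Pou5f1 (log2 change −0.14, SE 0.21, adjusted p = 0.667) and Zfp42 (0.10, adjusted p = 0.751) were not called. Sox2 at 0.86 (adjusted p = 0.00454), Klf4 at 0.63 (adjusted p = 0.0195) and Myc at −0.77 (adjusted p = 0.00998) passed the adjusted p but not 2-fold. Sox2 passed both with the authors' table (1.02) or without MEF replicate 1 (1.01), and Myc with median scaling (−1.11). In the pluripotency list 2 of 24 genes rose, Tdgf1 by 1.52 and Eras by 1.17 (0.89, under 2-fold, without MEF replicate 3), also 2 adjusted over the list alone, and the list did not pass (median 0.33, adjusted p = 0.0789).

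Most measured endoderm genes were higher at passage 5. Of 13 measured, 9 were called higher, also 9 adjusted over the list alone, with Sox17, Gata6 by 4.03 (16.3-fold, SE 0.15), Sox7 by at least 10.4-fold and Gata4 by 2.87, all transcription factors of early endoderm (list median 1.71, or 1.43 with bounds, adjusted p = 2.99e-08, and adjusted p = 0.161 with an estimated correlation). Within chips the median was 1.55 on chip 2 and 2.01 on chip 3. Germline genes rose in 5 of 6 (median 1.88, adjusted p = 2.40e-04, and adjusted p = 0.165 with an estimated correlation), with Stra8, a gene of meiotic entry, at least 9.19-fold higher and Rhox5 at 2.60. Endothelial genes passed upward with 2 of 7 higher, Vwf at 2.53 and Esam at 1.64, and 1 lower (median 0.76, or 0.69 with bounds, adjusted p = 0.0434, and adjusted p = 0.21 with an estimated correlation), but not with chip as a block (adjusted p = 0.0631), without MEF replicate 3 (median 0.69), without passage 5 replicate 1 (0.79), without both chip 3 arrays, or with only those groups in the fit. The cholesterol list also passed upward (median 0.44, adjusted p = 0.0212, and adjusted p = 0.312 with an estimated correlation), although none of its 16 genes reached 2-fold, and it failed without MEF replicate 1 (median 0.31).

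Fibroblast matrix and surface genes fell in 20 of 24 and rose in 1, Pdgfra, which is also a marker of primitive endoderm and was named after its value was seen (1.75). Counts adjusted over the list alone were the same (median −3.07, −2.06 on chip 2 and −4.23 on chip 3, adjusted p = 5.63e-15, adjusted p = 1.58e-09 with chip as a block, and adjusted p = 0.161 with an estimated correlation). Without passage 5 replicate 3 the list median was −2.34. Lox, the collagen cross-linking enzyme, fell by 4.17 (by 3.02 without passage 5 replicate 3 and by 4.91 without replicate 1) and Col6a1 was −3.99. Contractile genes fell in 10 of 12 (median −2.59, −2.11 and −3.54 within chips, adjusted p = 5.36e-09, and adjusted p = 0.161 with an estimated correlation), led by Acta2 at −4.37 (−3.42 without passage 5 replicate 3 and −4.98 without replicate 1) and Tagln at −3.53. Another of the 3 Acta2 probes gave −0.91. Mesenchymal transcription factors fell in 5 of 6 (median −2.52, −1.95 and −3.68 within chips, adjusted p = 2.74e-06, and adjusted p = 0.161 with an estimated correlation), with Prrx1 at −3.26 and Foxc2 at −3.01. Skeletal muscle genes fell in 7 of 9 (median −2.45, or −2.22 with bounds, adjusted p = 1.30e-08, and adjusted p = 0.161 with an estimated correlation), with Tnnc1 at −4.46.

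Chemokine and inflammation genes fell in 10 of 13 (median −1.59, −1.07 and −2.37 within chips, adjusted p = 1.97e-06, and adjusted p = 0.187 with an estimated correlation), including Ptgs2, the inducible cyclooxygenase, at −2.84 and the macrophage growth factor Csf1 at −2.79 (−1.85 without passage 5 replicate 3 and −3.41 without replicate 1). Without passage 5 replicate 3 the list median was −0.84. Imprinted genes fell in 5 of 12 (median −0.80, adjusted p = 3.47e-06, and adjusted p = 0.103 with an estimated correlation), with Igf2 at −3.08, Grb10 at −3.06, Dlk1 at −2.16 and Cdkn1c at −1.88. Smaller shifts downward were those of ATF4 genes (3 of 13 called, median −0.65, adjusted p = 0.00224, and adjusted p = 0.161 with an estimated correlation) and p53 targets (3 of 12, median −0.56, adjusted p = 0.0105, and adjusted p = 0.161 with an estimated correlation). Others were those of immediate early genes (4 of 8, median −0.80, adjusted p = 0.0189, and adjusted p = 0.165 with an estimated correlation) and of bone and cartilage genes (3 of 8 lower and 1 higher, median −0.27, adjusted p = 0.0411, and adjusted p = 0.244 with an estimated correlation). The bone list failed with chip as a block (adjusted p = 0.0571), without MEF replicate 3 (median −0.29) and without passage 5 replicate 1 (−0.22). The bone and endothelial lists also failed with the stricter detection filter, and p53 targets with the mean over probes (median −0.30). In lists given with one count, adjusting over the list alone gave the same count.

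limma called 1106 genes (11.8%), 454 higher and 652 lower at passage 5, and without a fold threshold the split turned to 1947 higher and 1417 lower. With chip as a fixed block it called 1111, and on chip 2 alone, with 2 arrays against 2, it called 836. All 14 lists that passed kept their direction on each chip, and all but the bone and endothelial lists passed with chip as a block. Median scaling moved the median change of all genes from 0.0491 to −0.0785 and the split from 454 higher and 652 lower to 376 and 822. With an estimated correlation 0 of 26 lists passed in camera, where 8 had an unadjusted p under 0.05.

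**Figure D2:**
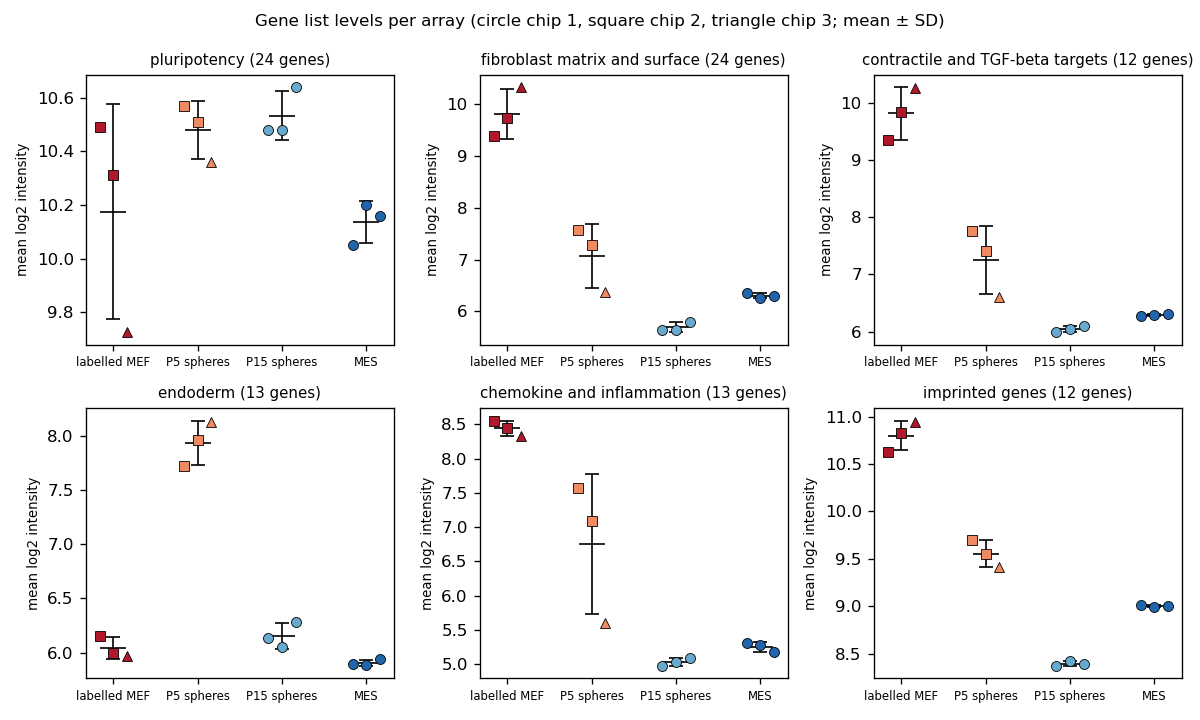
Mean log2 intensity of the measured genes of 6 lists on each of the 12 arrays, by group; circles are chip 1, squares chip 2 and triangles chip 3, and horizontal lines with bars give the mean and SD of 3 arrays. The endoderm list is highest at passage 5, the fibroblast list is highest in arrays labelled MEF, and the pluripotency list on those arrays reads 10.49, 10.31 and 9.72.

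Passage 15 spheres gave more calls against arrays labelled MEF, 2475 genes against 1106 at passage 5. Lox was 272-fold lower (log2 change −8.09, SE 0.69, n = 3 per group, adjusted p = 7.02e-07), Col1a1 at least 267-fold lower, Igf2 214.9-fold lower (−7.75, SE 0.24, adjusted p = 7.29e-10), the receptor kinase Axl at least 155-fold lower, Fbln2 at least 108-fold lower and Actg2 at least 116-fold lower. Thy1 fell by 6.28, Vim by 2.65 and Cd44 by at least 15-fold, though the other Cd44 probe gave −0.92. The largest rises were of the bile acid transporter subunit Slc51a by 4.42 (SE 0.17), the meiotic kinase Aurkc by 4.38 (SE 0.22), Stra8 by at least 14.5-fold, Wfdc2 by 3.84 (SE 0.23), Msc by 3.33 and Myo1f by 3.32.

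Pou5f1 rose by 1.06 (2.09-fold, SE 0.21, adjusted p = 7.44e-04), but stayed under 2-fold with the mean over its probes (0.32), without MEF replicate 3 (0.80) or without passage 15 replicate 3 (0.97). Sox2 at 0.98 passed the adjusted p but not 2-fold, which it passed without MEF replicate 1 (1.13), MEF replicate 2 (1.07) or passage 15 replicate 1 (1.01). The other of its 2 probes had the opposite sign (−0.30). Zfp42 (0.18, adjusted p = 0.459), Klf4 (0.05, adjusted p = 0.823) and Myc (0.46, adjusted p = 0.0602) were not called. The pluripotency list moved in both directions and did not pass (24 measured, 6 higher and 3 lower, also adjusted over the list alone, median 0.12, adjusted p = 0.547). Its largest rises were of Fgf4 by 2.63, Lefty2 by 2.20, Lefty1 by 2.16 and Eras by 1.77.

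Fibroblast matrix and surface genes fell in 22 of 24, the same count adjusted over the list alone (median −3.87, or −3.63 with bounds, adjusted p = 1.47e-13, and adjusted p = 0.275 with an estimated correlation). Contractile genes fell in 12 of 12 (median −3.88, or −3.60 with bounds, adjusted p = 9.65e-08, and adjusted p = 0.275 with an estimated correlation), with Ccn2 at −5.79 and Acta2 at least 49.6-fold lower by the probe used. Another of the 3 Acta2 probes gave −0.92, under 2-fold. Chemokine genes fell in 13 of 13 (median −3.62, or −3.05 with bounds, adjusted p = 6.33e-07, and adjusted p = 0.275 with an estimated correlation), with Csf1 at least 22.3-fold and Cxcl1 at least 22.1-fold lower. Mesenchymal transcription factors fell in 5 of 6 (median −3.69, or −3.01 with bounds, adjusted p = 2.29e-04, and adjusted p = 0.275 with an estimated correlation). Skeletal muscle genes fell in 6 of 9 (median −2.67, or −2.00 with bounds, adjusted p = 6.54e-05, and adjusted p = 0.275 with an estimated correlation). Counts adjusted over the list alone were the same for these 5 lists.

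Imprinted genes fell in 8 of 12 (median −1.92, adjusted p = 2.02e-06, and adjusted p = 0.0811 with an estimated correlation), with Dlk1 at −4.07 and Peg3 at least 14.3-fold lower beside Igf2. By its other probe Peg3 was −0.99. ATF4 genes fell in 6 of 13 and rose in 1, Xbp1 (median −0.90, adjusted p = 0.00393, and adjusted p = 0.275 with an estimated correlation), with Chac1 at −3.80 and Phgdh, the entry enzyme of serine synthesis, at −2.74. Interferon response genes fell in 5 of 12 and rose in 1 (median −0.93, or −0.58 with bounds, adjusted p = 0.00457, and adjusted p = 0.275 with an estimated correlation), with B2m, the light chain of class I antigen presentation, at −2.68. Immediate early genes fell in 4 of 8 (median −0.91, adjusted p = 0.00574, and adjusted p = 0.275 with an estimated correlation), with Egr1 at −3.40.

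Rises were seen in germline genes (5 of 6, median 1.61, adjusted p = 0.00574, and adjusted p = 0.275 with an estimated correlation). In cholesterol synthesis 7 of 16 rose (median 0.74, adjusted p = 0.00582, and adjusted p = 0.275 with an estimated correlation), with Insig1 at 3.26 (9.56-fold, adjusted p = 4.98e-07), Mvd at 1.64, Dhcr7 at 1.60 and Mvk at 1.51. Cell cycle genes passed upward with 6 of 21 higher and 2 lower (median 0.82, adjusted p = 0.00694, and adjusted p = 0.276 with an estimated correlation), with Pcna at 2.89 but the mitotic kinase Plk1 at −1.96 and the cyclin Ccna2 at −1.65. Endoderm genes did not pass here (13 measured, 2 higher and 2 lower, median 0.16, adjusted p = 0.944), nor did glycolysis and hypoxia genes, where 8 of 16 were called lower (median −0.98, adjusted p = 0.075), with Pgam1 at −1.83. Adjusting over each of these lists alone left the counts unchanged.

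limma called 2475 genes (26.5%), 1140 higher and 1335 lower at passage 15, and without a fold threshold the split turned to 3590 higher and 2663 lower. The groups were on different chips, so group and chip cannot be told apart in this comparison. In camera with an estimated correlation 0 of 26 lists passed, where 3 had an unadjusted p under 0.05.

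The passages were then set against each other. Gkn1 was at least 24-fold lower at passage 15, Sox17 at least 11.5-fold, Dab2 fell by 3.29 (SE 0.22, n = 3 per group) and Sox7 by 2.69 (SE 0.22). Igf2 fell by 4.66 (SE 0.24, adjusted p = 3.57e-08), the laminin chain Lamb1 by at least 18.8-fold, the lysyl oxidase Loxl2 by 4.63 (SE 0.30), the pepsinogen gene Pga5 by 4.55 (SE 0.22) and Srgn by 4.48 (SE 0.14). The largest rises were of Lypla1 by 3.29 (SE 0.42), Umps, an enzyme of pyrimidine synthesis, by 3.14 (SE 0.30), the RNA helicase Ddx5 by 3.12 (SE 0.53) and Psmd5 by 2.95 (SE 0.24). The other probe of Umps gave 0.20, under 2-fold. Bcat1 (3.33) and Ccnd3 (3.13) had further probes called in the opposite direction and stayed under 2-fold with the mean over probes (0.81 and 0.99).

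Pou5f1 rose by 1.20 (2.30-fold, SE 0.21, adjusted p = 4.62e-04), though by 0.36 with the mean over its probes, which differed in sign. Myc, a growth-promoting transcription factor, rose by 1.23 (SE 0.20, adjusted p = 2.76e-04), but stayed under 2-fold with the authors' table (0.73). Sox2 (0.12), Zfp42 (0.08) and Klf4 (−0.58) were not called, and in the authors' table, where another probe was brighter, Sox2 was −1.29. Col1a1 was at least 3.54-fold lower (5.36-fold without passage 5 replicate 3), Thy1 fell by 2.70 (adjusted p = 0.00233, by 3.73 without passage 5 replicate 3 and by 2.00 without replicate 1), Vim was −0.57 and not called (adjusted p = 0.0551), and Cd44 was at least 1.453-fold lower (adjusted p = 0.0106), a call lost without passage 5 replicate 1 (−0.83), with the mean over probes (−0.63) and with median scaling (−0.72). In the pluripotency list 4 of 24 rose and 4 fell, also adjusted over the list alone, led by Fgf4 at 2.71, Lefty2 at 2.13, Lefty1 at 1.81 and Tdgf1 at −1.67. That list did not pass (adjusted p = 0.847), with a median of 0.0399 and a mean of 0.0542 while the test pointed downward.

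Of 13 endoderm genes 9 fell, also 9 adjusted over the list alone (median −2.22, or −1.75 with bounds, adjusted p = 3.83e-05, and adjusted p = 0.311 with an estimated correlation). Chemokine genes fell in 10 of 13, or 11 adjusted over the list alone (median −1.83, or −1.46 with bounds, adjusted p = 9.27e-04, and adjusted p = 0.582 with an estimated correlation), with Cxcl12 at least 7.91-fold and Cxcl1 at least 6.41-fold lower (at least 4.03-fold without passage 5 replicate 1 and 12.3-fold without replicate 3). By its other probe Cxcl12 was −0.29. Glycolysis and hypoxia genes fell in 10 of 16 (median −1.08, or −1.06 with bounds, adjusted p = 0.00121, and adjusted p = 0.582 with an estimated correlation), with Egln3, Ndrg1 and P4ha1, all targets of the hypoxia-inducible factor, at −2.36, −2.13 (−2.73 without passage 15 replicate 3) and −2.11, and the glycolytic enzyme Pgam1 at −2.04. Fibroblast genes fell in 11 of 24 (median −0.67, or −0.60 with bounds, adjusted p = 9.27e-04, and adjusted p = 0.607 with an estimated correlation), with Lox at −3.92 (−5.06 without passage 5 replicate 3 and −3.18 without replicate 1), Pdgfra at −3.43 and Fbln2 at least 12.3-fold lower (23.3-fold without passage 5 replicate 3 and 8.21-fold without replicate 1). Contractile genes fell in 6 of 12 (median −1.03, or −0.92 with bounds, adjusted p = 0.00367, and adjusted p = 0.582 with an estimated correlation), with Ccn2 at −3.14.

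Imprinted genes fell in 6 of 12 (median −0.87, adjusted p = 0.00367, and adjusted p = 0.311 with an estimated correlation), with Peg3 at least 8.5-fold lower, or −0.62 on the log2 scale by its other probe. Interferon response genes fell in 4 of 12 (median −0.72, or −0.58 with bounds, adjusted p = 0.00367, and adjusted p = 0.561 with an estimated correlation), with B2m at −1.52, but not with median scaling (median −0.48). Neural and neural crest genes fell in 4 of 10 (median −0.91, or −0.31 with bounds, adjusted p = 0.0358, and adjusted p = 0.311 with an estimated correlation), with Gfap at least 2.82-fold lower, again not with median scaling (−0.33) or the stricter detection filter. Cell cycle genes passed upward with 4 of 21 higher and 2 lower (median 0.43, adjusted p = 0.0434, and adjusted p = 0.582 with an estimated correlation), with Cdca8 at 1.34 and Cdk1 at 1.19 (0.74, under 2-fold, with the mean over probes). This last list call was lost without passage 15 replicate 1 (0.44), passage 15 replicate 2 (0.43) or passage 5 replicate 1 (0.42) and with median scaling (0.59). Cholesterol genes, with 5 of 16 higher and 1 lower, missed the threshold (median 0.35, adjusted p = 0.0621) but passed without passage 15 replicate 3 (0.28) or passage 5 replicate 3 (0.39). Where no other count is given, counts adjusted over the list alone were the same.

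limma called 1591 genes (17%), 629 higher and 962 lower at passage 15, and without a fold threshold the split turned to 2783 higher and 2526 lower. Passage 15 was on chip 1 and passage 5 on chips 2 and 3, and median scaling, which moved the median change of all genes from 0.00731 to 0.175, turned the split to 1214 higher and 742 lower, so the balance of directions is not given as a result. With an estimated correlation 0 of 26 lists passed in camera, where 3 had an unadjusted p under 0.05.

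**Figure D3:**
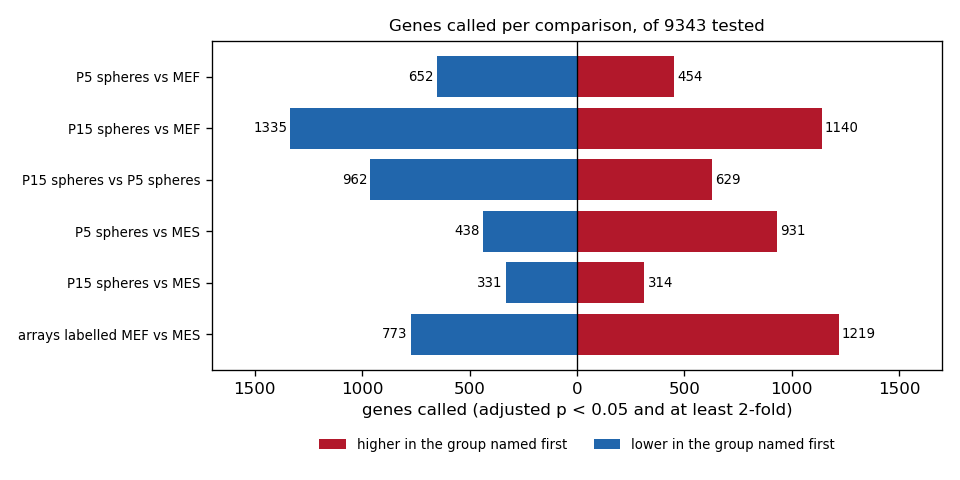
Number of genes called by limma in each of the 6 comparisons at an adjusted p under 0.05 and at least 2-fold, with genes higher in the first group in red and lower in blue. The count is lowest for passage 15 spheres against MES at 645 and highest for passage 15 spheres against arrays labelled MEF at 2475.

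Passage 5 spheres were also set against the MES reference. Srgn was 44-fold higher (log2 difference 5.46, SE 0.14, n = 3 per group, adjusted p = 9.48e-11), Foxq1 34.6-fold, the endocytic adaptor Dab2 27.4-fold, Gkn1 at least 24.7-fold, Lamb1 at least 19.3-fold and Sox17 at least 11.8-fold higher. Pigt was 58.4-fold higher by the probe used, and 0.58 on the log2 scale by the lowest of its 2 probes. Genes lower than in MES were Ccnd3 (−2.84), Cdx1 (−2.74), the carbonyl reductase Cbr3 (−2.56), Sfn (−2.38), the quinone reductase Nqo1 (−2.28) and the helix-loop-helix factor Id1 (−2.27). The other probe of Ccnd3 had the opposite sign (0.24).

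Pou5f1 was 2.44-fold lower at passage 5 than in MES (log2 difference −1.29, SE 0.21, adjusted p = 3.35e-04), but −0.61 with the mean over its probes. Klf4 was 3.01-fold higher (1.59, adjusted p = 2.68e-05) and Myc 2.78-fold lower (−1.48, adjusted p = 8.17e-05), although Myc stayed under 2-fold with the authors' table (−0.92). The lowest of the 3 Klf4 probes gave 0.67, under 2-fold. Sox2 (0.64, adjusted p = 0.0164) and Zfp42 (0.74, adjusted p = 0.00946) did not reach 2-fold, and Sox2 did with the authors' table (1.99) and with the mean over probes (1.41). Vim (0.05), Col1a1 (0.58, adjusted p = 0.258) and Thy1 (−1.07, adjusted p = 0.158) were not called. Col1a1 was called without passage 5 replicate 3 (1.18) and Thy1 without passage 5 replicate 1 (−1.76), while without passage 5 replicate 3 Thy1 was −0.04. Cd44 was at least 1.49-fold higher (adjusted p = 0.0118), a call lost without passage 5 replicate 1 (0.83), with the mean over probes (0.70) and with median scaling (0.75).

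Endoderm genes were higher in 9 of 13, also 9 adjusted over the list alone (median 1.80, or 1.66 with bounds, adjusted p = 2.64e-07, and adjusted p = 0.446 with an estimated correlation), with Gata4 at 3.31 and Spink1 at 2.75. Chemokine genes were higher in 9 of 13, or 10 adjusted over the list alone (median 1.77, or 1.5 with bounds, adjusted p = 0.00327, and adjusted p = 0.745 with an estimated correlation), with Cxcl12 at 2.84, and without passage 5 replicate 1 the list median was 0.98. By its other probe Cxcl12 was at 0.03. Glycolysis genes were higher in 7 of 16 and lower in 1 (median 0.95, adjusted p = 0.00759, and adjusted p = 0.745 with an estimated correlation), with P4ha1 at 2.45. Contractile genes were higher in 5 of 12 (median 0.98, or 0.77 with bounds, adjusted p = 0.00759, and adjusted p = 0.745 with an estimated correlation), with Tgfbi at 2.11. Interferon response genes were higher in 4 of 12 (median 0.55, or 0.51 with bounds, adjusted p = 0.00759, and adjusted p = 0.745 with an estimated correlation), with Psmb9 at 1.82, but not with median scaling (0.25). Hox genes were higher in 3 of 14, Hoxa7 at least 5.62-fold, Hoxa5 at 2.59 and Hoxb4 at 1.24 (median 0.63, or 0.44 with bounds, adjusted p = 0.0142, and adjusted p = 0.745 with an estimated correlation), but not with median scaling (0.07), without background correction (0.96) or, for Hoxb4 alone, with the authors' table (0.88).

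Fibroblast genes were higher in 7 of 24, or 6 adjusted over the list alone (median 0.51, or 0.37 with bounds, adjusted p = 0.0341, and adjusted p = 0.745 with an estimated correlation), with Pdgfra at 3.73 and Dcn at least 15.6-fold higher (25.4-fold without passage 5 replicate 3). The lowest of the 4 probes of Dcn gave 0.04 on the log2 scale. The list call was lost without MES replicate 1 (0.49), passage 5 replicate 1 (0.16) or passage 5 replicate 2 (0.28) and with the stricter detection filter (0.57), and with median scaling the median was −0.00562. Pluripotency genes did not pass (5 higher and 2 lower of 24, median 0.34, adjusted p = 0.187), with Lefty1 at 2.59 and Tdgf1 at 2.08. Among imprinted genes, which did not pass either (4 higher and 1 lower of 12, adjusted p = 0.185), Igf2 was 3.47 higher and Phlda2 was −1.83. The other counts held when adjusted over the list alone.

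limma called 1369 genes (14.7%), 931 higher and 438 lower at passage 5, and without a fold threshold the split turned to 2353 higher and 2638 lower. Group and chip cannot be told apart here, and median scaling, which moved the median of all genes from −0.0517 to −0.219, turned the split to 741 higher and 997 lower. In camera with an estimated correlation 0 of 26 lists passed, where 2 had an unadjusted p under 0.05.

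Passage 15 spheres and MES shared chip 1 and gave the fewest calls, 645 genes. The Nodal inhibitors Lefty1 and Lefty2 were higher in the spheres, by 4.41 (21.2-fold, SE 0.21, n = 3 per group, adjusted p = 1.95e-07) and by 3.29 (SE 0.28, adjusted p = 5.87e-06). The fatty acid transporter Slc27a2 was 10.4-fold, the homeobox gene Hoxa5 9.41-fold, Sox21 7.83-fold and Aurkc 7.61-fold higher. Thy1 was 13.6-fold lower than in MES (−3.76, SE 0.61, adjusted p = 7.58e-04), Pglyrp1 at least 9.36-fold, Lox 9.45-fold, the glutathione peroxidase Gpx2 8.97-fold, Fbln2 at least 7.98-fold and Anxa3 8.52-fold lower.

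Pou5f1 did not differ detectably (log2 difference −0.08, SE 0.21, adjusted p = 0.825), and neither did Myc (−0.25, adjusted p = 0.398) or Vim (−0.52, adjusted p = 0.119). Sox2 at 0.76 (adjusted p = 0.0129) and Zfp42 at 0.82 (adjusted p = 0.0113) passed the adjusted p but not 2-fold. Klf4 was called at 1.01 (adjusted p = 0.00188), but not without MES replicate 1 (0.93), without passage 15 replicate 3 (0.83), with the mean over probes (0.48) or with the authors' table (0.97). Col1a1 was at least 2.36-fold lower (adjusted p = 0.0132), a call lost without MES replicate 1 (−1.47), with the authors' table (−0.97) and with median scaling (−1.16). The Cd44 probe used was not above background in either group.

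Epithelial junction and keratin genes were lower in 6 of 15, also 6 adjusted over the list alone (median −0.47, adjusted p = 0.015, and adjusted p = 0.436 with an estimated correlation), with the keratins Krt8 at −2.55, Krt18 at −1.72 and Krt7 at least 4.9-fold lower and the claudin Cldn4 at −1.65. Imprinted genes were lower in 5 of 12, also 5 adjusted over the list alone (median −0.65, adjusted p = 0.015, and adjusted p = 0.436 with an estimated correlation), with Phlda2 at −1.58, Cdkn1c at −1.13, and Igf2 at −1.19 or −0.90 with the authors' table. Both list calls were lost without MES replicate 2 (medians −0.51 and −0.61). No other list passed. Pluripotency genes had a median of 0.02 (4 higher and 1 lower of 24, adjusted p = 0.487), fibroblast genes of −0.16 (4 lower of 24, adjusted p = 0.141) and endoderm genes of 0.03 (2 higher of 13, adjusted p = 0.487).

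limma called 645 genes (6.9%), 314 higher and 331 lower at passage 15, and without a fold threshold the split turned to 1379 higher and 1232 lower. The spheres were of strain FVB/N and MES of another strain, so strain and cell type cannot be told apart. With an estimated correlation 0 of 26 lists passed in camera, where 2 had an unadjusted p under 0.05.

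The position of each sphere array was then placed on the axis from arrays labelled MEF (0) to MES (1). Over the 773 genes higher in MES, passage 5 spheres lay at 0.405 ± 0.0653 (SD, n = 3) and passage 15 spheres at 0.934 ± 0.0567. Over the 1219 genes higher in arrays labelled MEF, passage 5 spheres lay at 0.53 ± 0.0648 and passage 15 spheres at 1 ± 0.0333. All 3 passage 15 arrays lay nearer MES than all 3 passage 5 arrays on both gene sets, with p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 arrays can give. Passage 15 shares chip 1 with MES and passage 5 shares chips with the arrays labelled MEF, so passage and chip cannot be told apart in these positions.

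**Figure D4:**
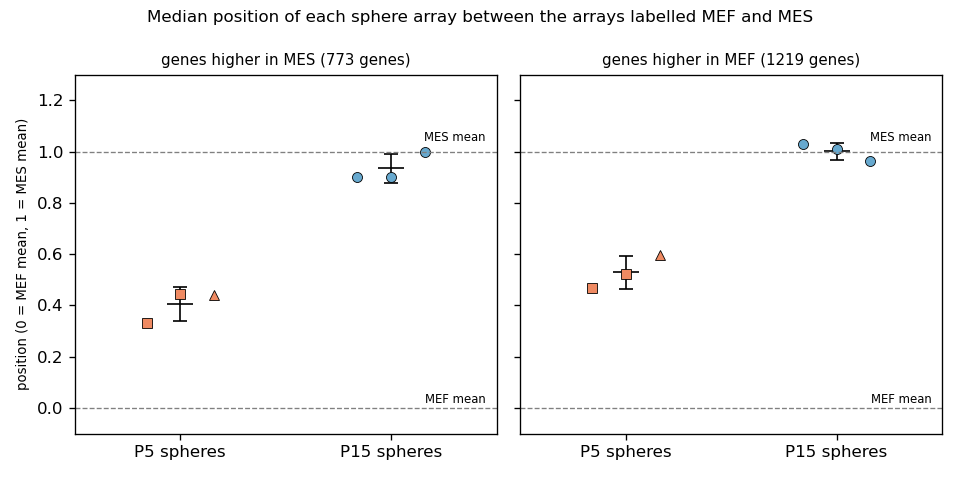
Median position of each sphere array on a scale where 0 is the mean of arrays labelled MEF and 1 the MES mean, over 773 genes higher in MES and 1219 genes higher in arrays labelled MEF; circles are chip 1, squares chip 2 and triangles chip 3, and lines with bars give the mean and SD of 3 arrays. Passage 5 arrays lie between 0.33 and 0.597, and passage 15 arrays between 0.901 and 1.03.

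Genes called against arrays labelled MEF at both passages mostly moved the same way. Of 652 genes lower at passage 5, 612 (93.9%) were also lower at passage 15, where independent lists would share 93.2. Of 454 genes higher at passage 5, 246 (54.2%) were also higher at passage 15, where independent lists would share 55.4. Another 14 genes were called in opposite directions. Both comparisons use the same arrays labelled MEF, which are too few to divide, so the overlap is not independent of them. In 20 simulated runs with unchanged groups against the shared arrays, an unadjusted p under 0.05 gave an overlap of 82.3 genes on average, where the observed overlap at that p was 2833. With the calls by limma the simulated overlap was 0, which says little as unchanged groups give hardly any call. The contrast at the unadjusted p says little either, since the simulation held no changed gene. In the data 4137 genes had that p at passage 5 and 6491 at passage 15, so a far larger overlap would arise without shared changes.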

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

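The limit to genes detected on all 6 arrays labelled MEF or MES was chosen only after the result was seen, while the other tests here were planned.

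For 9 gene lists the change against MES differed between the passages. MES cancels from this difference, so these are the list results between the passages given above. The difference itself was tested with camera on passage 15 against passage 5 at the preset correlation, and 0 of 26 lists passed with an estimated correlation, where 3 had an unadjusted p under 0.05. Endoderm genes differed by a median of −2.22 on the log2 scale (adjusted p = 3.83e-05, and adjusted p = 0.311 with an estimated correlation), with medians against MES of 1.80 at passage 5 and 0.03 at passage 15. Chemokine and inflammation genes differed by −1.83 (adjusted p = 9.27e-04, and 0.582 with an estimated correlation), from 1.77 to −0.15. The difference for glycolysis and hypoxia genes was −1.08 (adjusted p = 0.00121, and 0.582 with an estimated correlation), from 0.95 to −0.09. Contractile genes differed by −1.03 (adjusted p = 0.00367, and 0.582 with an estimated correlation), from 0.98 to −0.03. Neural and neural crest genes differed by −0.91 (adjusted p = 0.0358, and 0.311 with an estimated correlation), from 0.97 to 0.02. Imprinted genes differed by −0.87 (adjusted p = 0.00367, and 0.311 with an estimated correlation), from 0.37 to −0.65. Interferon response genes differed by −0.72 (adjusted p = 0.00367, and 0.561 with an estimated correlation), from 0.55 to −0.02. Fibroblast genes differed by −0.67 (adjusted p = 9.27e-04, and 0.607 with an estimated correlation), from 0.51 to −0.16. The cell cycle list differed by 0.43 (adjusted p = 0.0434, and 0.582 with an estimated correlation), from −0.25 to 0.30. With median scaling the interferon, neural and cell cycle lists did not pass.

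The passages sat on different chips, so an offset between chip 1 and chips 2 and 3 may lie behind the 1591 genes called between them. Such an offset would also part MES from the arrays labelled MEF. Yet 336 of the called genes (21.1%) had a MES minus MEF difference under 0.5 on the log2 scale. Of the called genes detected on all 6 arrays, 241 did (20.2%). This argues against an offset for those genes only if no opposite difference between the cells cancelled it, which the design cannot show. For 1039 genes (65.3%) the MES minus MEF difference had the same sign and at least 0.5 times the size, so that an offset and a difference between the cells cannot be told apart, because no chip held both passages. The other 216 genes (13.6%) met neither description. A biological difference between the passages stays open as untested.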

How the results depend on the processing

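Leaving out both chip 3 arrays was chosen only after the data were seen, and all other alternatives were planned.

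Across the alternatives, named genes stayed on the same side of the threshold in 10678 cases, lost the call in 387, gained it in 91 and reversed in 3. Among the 10678 were 33 genes not called either way that took the other sign. The gene lists at the preset correlation stayed on the same side in 2435 cases, lost the call in 33, gained it in 54 and reversed in 0, for camera with limma. With an estimated correlation 0 lists passed in each of the 6 comparisons, from 14, 12, 9, 7, 2 and 14 in the order used below, with lowest adjusted p of 0.103, 0.0811, 0.311, 0.446, 0.436 and 0.194. The order of comparisons is passage 5 against MEF, passage 15 against MEF, passage 15 against passage 5, passage 5 against MES, passage 15 against MES, and MEF against MES. The reversals were Sox2 between the passages with the authors' table (−1.29), where another probe was brighter, and Hoxc8 without background correction in passage 15 against MEF (0.56) and MEF against MES (−0.63). These Hoxc8 values lay near those of its other probe in the main setting (0.51 and −0.57), so a change of the brightest probe may account for them. Without a fold threshold, which admits small changes, limma called 3364, 6253, 5309, 4991, 2611 and 5825 genes. With the authors' table it called 758, 1705, 920, 788, 315 and 1282 genes, the last 4 of them more than 1.5 times fewer, and the cause was not tested. Without background correction it called 1204, 2735, 1935, 1615, 745 and 2185. Leaving out each array in turn gave 957 to 1279, 2261 to 2637, 1540 to 1670, 1300 to 1490, 530 to 743 and 1714 to 2158 genes, so no array moved a count by over 1.5 times. Without both chip 3 arrays limma called 827, 2260, 1561 and 1300 genes in the first 4 comparisons and 1713 in the last. With chip as a random block (correlation 0.121) it called 1108, 2497, 1599, 1380, 649 and 1996, and with the replicate number as a block 1108, 2476, 1592, 1371, 648 and 1994. Lists passing for passage 5 against MES fell to 4 with median scaling, and for passage 15 against MES rose to 4 without a filter and with only those groups in the fit, where the cause was not tested. For the latter comparison, leaving out each array gave 0 to 2 lists, the 0 being without MES replicate 2. Positions of passage 5 moved to 0.606 with the authors' table and 0.449 without background correction over genes higher in MEF, and to 0.315 with median scaling over genes higher in MES, where the cause was not tested. Over genes higher in MES, leaving out each array gave 0.332 to 0.443 for passage 5, lowest without MES replicate 1, and 0.851 to 0.973 for passage 15, lowest without MES replicate 2. The random chip block and the missing fold threshold were not run for lists. Signal over background limits folds for genes not detected in a group, which are given as bounds.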

Other observations

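All tests of explanations here were chosen only after the results were seen, apart from the splits of the arrays, which were planned.

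Some genes of lipid storage and use were higher in the spheres than in arrays labelled MEF, though not in the spheres alone. Cidea was also at least 3.4-fold higher in MES than in arrays labelled MEF. Acss2 had a log2 difference of −2.29 in arrays labelled MEF against MES, or −0.52 by its other probe. Cidea, a protein of lipid droplets, was at least 6.88-fold higher at passage 15 than in arrays labelled MEF (adjusted p = 1.66e-07), Lpl, the lipoprotein lipase, 2.60 higher on the log2 scale (SE 0.14) and Acss2, which makes acetyl-CoA from acetate, 3.07 higher. At passage 5 Lpl was 1.60 and Acss2 2.72 higher, though the other probe of Acss2 gave −0.05. The adipocyte and lipid storage list did not pass at passage 15 against arrays labelled MEF (3 higher and 1 lower of 9, median 0.07, adjusted p = 0.586). Neither did fatty acid synthesis (2 higher and 1 lower of 12, median 0.20, adjusted p = 0.758) or fatty acid oxidation and PPAR targets (3 higher of 8, median 0.78, adjusted p = 0.222), where Acadm, the medium-chain acyl-CoA dehydrogenase, was 1.53 higher. At passage 5 the oxidation list missed the threshold (adjusted p = 0.0508) and passed with chip as a block (adjusted p = 0.0299), as glycolysis did (adjusted p = 0.0655 and 0.00973). With an estimated correlation and no block, the oxidation list gave adjusted p = 0.266 and glycolysis adjusted p = 0.559.

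In the same comparison at passage 15, Hoxa5 was 2.95 higher while Hoxc6 was at least 5.13-fold lower, and the Hox list did not pass (2 higher and 7 lower of 14, median −0.87, adjusted p = 0.075). NRF2 targets (1 higher and 3 lower of 9, adjusted p = 0.586) had a median of 0.227 and a mean of −0.228 while the test pointed downward, with the heme oxygenase Hmox1 at −1.62. Mesoderm genes did not pass (3 lower of 11, median −0.26, adjusted p = 0.219), with Wnt5a at least 10.3-fold lower. Among 9 housekeeping genes, Actb was −1.20 and Ywhaz −1.72, and the list median was −0.13. Xist, the transcript of X inactivation, was −2.38 at passage 15 and −2.59 at passage 5 against arrays labelled MEF, the called one of 2 measured sex-linked genes. Laptm5 was the 1 macrophage and blood gene measured and was not called (0.33). Of 2 measured keratinocyte genes, Sfn was 1.20 higher (0.86 with the authors' table). The probes of 28 of 156 named gene and comparison pairs with several probes differed in sign, and for 3 pairs, Bcat1, Ccnd3 and Tbp between the passages, they were called in opposite directions. The call of Tbp (−1.65) was lost without passage 15 replicate 3 (−0.72). Of 129 such pairs called by the probe used, 67 had another probe with a change under 2-fold, so the size of a change can depend on the probe.

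Pluripotency transcripts were detected in the arrays labelled MEF. Probes reading background are argued against, since 84.6% of pluripotency genes but 7.14% of macrophage and blood genes passed detection on all 3 of these arrays. A swap with another group is argued against too, since for 22 of 24 fibroblast genes the lowest of these arrays lay above every other array. A candidate explanation is RNA of pluripotent cells mixed with that of fibroblasts: on chip 3 against chip 2 the pluripotency list changed by −0.68 (24 of 24 genes) and the fibroblast list by 0.81, opposite ways as a mixture would give, though passage 5 also showed −0.15 (19 of 24) for pluripotency. For chip 3 this rests on replicate 3 alone. Dilution of cells like MES would also put the list below its MES level. Its mean log2 level was 10.49, 10.31 and 9.72 on arrays labelled MEF and 10.05, 10.2 and 10.16 in MES, on another chip. Only replicate 3 lay below MES. The mean cannot show that dilution was absent on the other arrays, since MES was on another chip and list genes differed from MES in both directions. Every array labelled MEF lay below the passage 5 arrays of its own chip (10.57 and 10.51 on chip 2, 10.36 on chip 3). Dilution of cells like those spheres was not tested. Expression of these genes in the fibroblasts themselves, or in cells of another origin, was not tested, and the labels name no sort.

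Fibroblast transcripts differed among arrays of the same group. An offset of chip 3 shared by both groups and acting alone is argued against, as the fibroblast list on chip 3 against chip 2 changed by −0.51 at passage 5 but by 0.81 in arrays labelled MEF. Each group had replicate 3 alone on chip 3, so an offset beside opposite differences between those arrays cannot be excluded. Unequal amounts of fibroblast RNA may account for the change at passage 5, where contractile genes changed by −0.96 and housekeeping genes by 0.04. Mesenchymal transcription factors changed by −0.34 (quartiles −0.71 and −0.24), short of the 0.5 set for this test, so the prediction failed as written. The quartiles lie on both sides of that bound, which was judged only after the value was seen. They describe the spread between genes and not between arrays. With replicate 3 alone on chip 3, the explanation is left open. No biological explanation was tested here.

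The 3 against 3 arrays of each comparison make 10 splits, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes. The real counts were 1106, 2475, 1591, 1369, 645 and 1992, in the order passage 5 against MEF, passage 15 against MEF, passage 15 against passage 5, passage 5 against MES, passage 15 against MES, and MEF against MES. The highest other split gave 0 genes in limma each time, and up to 748, 415, 335, 449, 924 and 658 at an unadjusted p under 0.05.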
